A study of Mus musculus with 24 samples.

How the data were processed

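The series holds 24 libraries of polyA RNA from C57BL/6J mice, prepared with Trizol and TruSeq kits and sequenced as paired ends. Groups were taken from the titles: endothelium and stroma of the marrow, each in culture, alone, with HSPC and in vivo, with 3 libraries per group. The deposited FPKM values were made by the authors with TopHat and Cufflinks on the mouse genome build mm9, according to the submitters' processing notes, which give no versions. The files give one FPKM to 2 decimals for each gene symbol. Library totals differ from each other and are higher than plain FPKM usually gives, so a further scaling by the authors is possible but not stated.

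Depth was not stated, and counts were not used here. Values of the lowest genes were searched for steps that single reads would leave, and no depth could be read from them. The fullest bin of a pair of libraries held at most 3.97% of the values and between 2 and 4.96 times the median bin, and no limit for a step was set beforehand. The precision that depth gives each library is therefore unknown, and the spread between the 3 libraries of a group is the only measure of error. Genes listed at 0 per library numbered 9128 to 10756. The upper quartile over all genes ran from 49.15 to 58.9 FPKM. The 10 genes with the highest values held 4.01% to 17.03% of a library's total.

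All comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined, except where the closing section says otherwise. The values were taken as deposited, with log2(FPKM + 1) as the scale. In all, 3 fits with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) each took 12 libraries of 4 groups: culture and in vivo, alone and with HSPC, and culture and alone. Genes with an FPKM of at least 1 in at least 3 libraries of the fit were tested. From these fits 12 comparisons were drawn, of which 2 were interactions that asked whether a change differed between the cell types. Calls used a Benjamini-Hochberg adjusted p under 0.05 over all tested genes.

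Gene groups came from 25 lists of textbook markers with 446 entries, of which 443 were found in the files. Ly6g, Ahsp and Hmgcs1 were missing. The lists were endothelial identity, sinusoidal endothelium, arterial endothelium, mesenchymal matrix, Lepr-positive stroma, osteoblast, adipocyte, smooth muscle and pericyte, HSC niche factors, pan-hematopoietic, granulocyte, monocyte and macrophage, erythroid, megakaryocyte, lymphoid, HSPC, cell cycle, interferon response, NF-kB and cytokine response, cholesterol synthesis, hypoxia and glycolysis, immediate-early, Notch targets, TGF-beta and BMP targets, and FoxO targets. Of these, 16 share no gene with another list. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with the adjustment over the lists of a comparison, and again with a correlation estimated from the residuals. Members called were counted both over all genes and adjusted over the list alone.

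Genes were named by a rule. It took Akt1, the 8 largest rises and 8 largest falls among called genes whose 3 libraries of one group all lay above those of the other with a mean FPKM of at least 5 in the higher group, and up to 4 called members of each list with the largest change. Clone names, microRNA, small nucleolar and histone cluster genes were left out. Further list members could be named to describe a list, which was used for Car9 in stroma. Xist and the Y-linked genes were chosen after their values were seen.

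Simulated tests changed 200 genes with a mean log2 level above 4 and gave each gene the same spread in all groups. At a log2 change of 1 the share recovered was 54% for endothelium against stroma in culture, 56% in vivo, 53% for endothelium in vivo against culture, 56% for stroma and 31% for their interaction. It was 98%, 98% and 97% for HSPC in endothelium, in stroma and for the interaction, 98% for the cell types alone and 98% with HSPC, and 62% and 67% for alone against culture in endothelium and stroma. At a log2 change of 2 these shares were 86%, 81%, 86%, 89%, 82%, 99%, 100%, 98%, 100%, 100%, 88% and 89%. False calls in the same order made up 5.41% (5.405%), 5.52%, 7.33%, 9.38% (9.375%), 5.83%, 4.83%, 2.94%, 6.70%, 7.04%, 7.48%, 5.06% and 4.29% of calls.

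Alternatives were a pseudocount of 0.1, no filter, a filter at an FPKM of 5, trimmed-mean scaling (trims of 0.3 and 0.05), quantile normalization, only the compared groups or all 8 groups in the fit, a weight per group, the replicate number as a block, a change of at least 2-fold, and each library left out in turn. Added after seeing the data were fits without the cultured libraries that carry Xist, and a restriction to genes with a mean FPKM of at least 1 without HSPC. A count was called moved when it changed by more than 1.5 times. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Reads, read counts and transcript isoforms were not used here.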

Results

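Transcript levels were measured in endothelial cells and stromal cells of mouse bone marrow (C57BL/6J). The 24 libraries form 8 groups of 3. Each cell type was profiled in culture, in a second culture series without and with added hematopoietic stem and progenitor cells (HSPC), and in vivo. The groups of the second series are called alone and with HSPC here. The series is about the arteriolar niche of hematopoietic stem cells, and its labels ask how both cell types differ between culture and the marrow and how they respond to HSPC. Titles of all 18 libraries from cells in culture, with and without HSPC, carry the name Akt1, a kinase of the insulin and growth factor pathway, without saying what was done to it. The 6 titles from cells in vivo lack it. Every comparison of in vivo with culture therefore also sets libraries without that name against libraries with it. Any difference in how the cells were isolated cannot be told apart from the setting in these comparisons either.

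The deposited values were FPKM (fragments scaled by transcript length and library size) for 23879 gene symbols per library. Between 12447 and 13961 genes reached an FPKM of 1, and the totals ran from 1421447 to 1808592 FPKM per library. No read counts were used here, so the depth behind each value is unknown. Levels are given as mean FPKM ± SD (n = 3), and log2 differences, taken on log2(FPKM + 1), carry their SE. That scale understates the change of genes with low levels. Nothing in the labels says that the 3 libraries of a group came from separate cultures or animals, so the adjusted p-values of limma measure only the spread between these libraries, which may be technical.

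Libraries of one group correlated across genes between 0.9947 and 0.9982 in the 4 groups alone and with HSPC, and between 0.9948 and 0.9961 in vivo. The cultured groups were wider, from 0.9624 to 0.9717 for endothelium and from 0.9539 to 0.9927 for stroma, where replicate 1 stood apart from replicates 2 and 3. Over the adipocyte list the mean log2(FPKM + 1) in cultured stroma was 2.45, 7.10 and 6.32 in replicates 1 to 3, and over the hypoxia and glycolysis list 8.56, 6.93 and 6.58 (6.585). In cultured endothelium replicate 2 stood apart on the arterial list (8.81, 6.07 or 6.065, and 8.57) and on Notch targets (4.197, 2.73 and 4.25). Genes are not independent replicates in these correlations. Xist, the transcript that silences one X chromosome in female cells, stood at 1107 and 1250 FPKM (1249.8) in cultured endothelial replicates 2 and 3 and at 1006 in cultured stromal replicate 3. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in these 3 libraries and reached at least 30.7 in each of the other 21, where Xist was at most 2.35. Every comparison with a cultured group therefore holds libraries that differ in these genes.

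Akt1 itself reached 1672 ± 632 in cultured endothelium, 1104 ± 20.5 alone, 1814 ± 50.4 with HSPC and 445 ± 21.3 in vivo. In stroma its level was 619 ± 89.5 in culture, 634 ± 17.1 alone, 493 ± 29.3 with HSPC and 258 ± 25.3 in vivo. With HSPC it rose in endothelium by 0.71 ± 0.05 and fell in stroma by a log2 difference of -0.36 ± 0.05, and these effects differed by 1.08 ± 0.06 (adjusted p = 1.86e-07). From culture to in vivo it changed by -1.84 ± 0.24 in endothelium and -1.26 ± 0.24 in stroma, and the test of that difference gave adjusted p = 0.218 at -0.58 ± 0.34. Between the cultures alone and the first cultures the differences were -0.53 ± 0.24 in endothelium (adjusted p = 0.131) and 0.04 ± 0.24 in stroma (adjusted p = 0.922).

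In culture, endothelial cells and stroma were separated by their junction, vessel and matrix genes. Among the endothelial identity genes, 26 of 26 measured were higher in endothelium (26 adjusted over the list alone, camera adjusted p = 4.18e-22, adjusted p = 0.00597 with an estimated correlation), among them the junction genes Pecam1 (3269 ± 1024 against 4.56 ± 1.04, log2 difference 9.17 ± 0.25), Cdh5 (2449 ± 1034 against 3.49 ± 0.525) and Icam2 (2058 ± 501 against 2.95 ± 0.776). Arterial genes were higher for 18 of 19 members (18 adjusted over the list alone, camera adjusted p = 7.00e-08, adjusted p = 0.299 with an estimated correlation). Among them were the gap junction genes Gja5 (3317 ± 2564 against 1.92 ± 3.33, log2 difference 10.10 ± 0.95) and Gja4 (2377 ± 2092 against 1.59 ± 2.75), the kinase gene Bmx (288 ± 238 against 0.230 ± 0.398) and the transcription factor gene Sox17 (304 ± 242 against 0.210 ± 0.364). Of 7 Notch targets, 3 were higher (3 adjusted over the list alone, camera adjusted p = 0.140). An example was Nrarp (507 ± 251 against 0.697 ± 1.21, log2 difference 8.29 ± 0.51), a feedback regulator of the pathway. The HSPC list, whose members Fgd5, Tal1 and Procr endothelial cells also express, had 7 of 15 higher and 2 lower (9 adjusted over the list alone, camera adjusted p = 0.0196, adjusted p = 0.299 with an estimated correlation). Examples were Fgd5 (208 ± 8.07 against 0.427 ± 0.0709) and Tal1 (89.4 ± 11.5 against listed at 0).

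Matrix genes ran the other way in culture. Of 23 mesenchymal matrix genes, 19 were lower in endothelium and 4 did not pass (19 adjusted over the list alone, camera adjusted p = 2.89e-13, adjusted p = 0.202 with an estimated correlation), with the collagen genes Col1a2 (0.913 ± 0.406 against 3271 ± 1547, log2 difference -10.63 ± 0.43), Col1a1 (1.30 ± 0.711 against 1907 ± 569) and Col6a1 (0.497 ± 0.430 against 1487 ± 979) among the former. Bone genes were lower for 8 of 13 (9 adjusted over the list alone, camera adjusted p = 3.42e-04, adjusted p = 0.299 with an estimated correlation). Among them were Spp1 (14.9 ± 6.03 against 66183 ± 43335, log2 difference -11.74 ± 0.65), the bone matrix protein osteopontin, and Runx2 (2.28 ± 0.711 against 51.8 ± 5.66), the master regulator of osteoblasts. Stroma also led in 6 of 9 adipocyte genes (7 adjusted over the list alone, camera adjusted p = 0.00174, adjusted p = 0.461 with an estimated correlation). Members included the fat cell regulator Cebpa (1.12 ± 0.978 against 184 ± 136) and the lipid droplet gene Plin4 (0.320 ± 0.306 against 76.7 ± 52.9). That lead rested mostly on replicates 2 and 3 of cultured stroma. The lead of stroma covered 6 of 14 smooth muscle and pericyte genes (6 adjusted over the list alone, camera adjusted p = 0.0163, adjusted p = 0.461 with an estimated correlation). An example was the pericyte marker Cspg4 (listed at 0 against 177 ± 103). Mgp (75.9 ± 20.7 against 43204 ± 26987), an inhibitor of calcification, followed the same direction.

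The cultured cell types differed in pathways as well. Cholesterol synthesis genes were lower in endothelium for 16 of 20 and higher for 1 (17 adjusted over the list alone, camera adjusted p = 1.98e-05, adjusted p = 0.471 with an estimated correlation). Lanosterol synthase, Lss (10.3 ± 6.85 against 79.8 ± 33.3, log2 difference -3.00 ± 0.45), and the enzyme gene Hsd17b7 (25.2 ± 12.4 against 114 ± 3.22) were lower. Interferon response genes were higher for 11 and lower for 1 of 24 (15 adjusted over the list alone, camera adjusted p = 0.00580, adjusted p = 0.397 with an estimated correlation). The tetherin gene Bst2 (1269 ± 358 against 149 ± 79.7) was higher and Ifit2 (9.48 ± 2.09 against 52.1 ± 20.1) lower. TGF-beta and BMP targets went both ways, 2 higher and 6 lower of 14 (9 adjusted over the list alone, camera adjusted p = 0.308). Lower were the matricellular genes Thbs1 (164 ± 86.5 against 4048 ± 455) and Tgfbi (4.06 ± 3.02 against 873 ± 601). In all, 5765 of 14904 tested genes differed, 2995 higher and 2770 lower in endothelium. With the spread taken from these 6 libraries alone the count was 2801, and with a weight per group 3546.

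In vivo, the endothelial libraries carried the genes of marrow sinusoids, and the stromal libraries those of bone and of the Lepr-positive stroma that surrounds sinusoids. Endothelial identity genes were higher for 26 of 26 (26 adjusted over the list alone, camera adjusted p = 8.10e-18, adjusted p = 0.0124 with an estimated correlation). Among them were Cldn5 (2642 ± 275 against listed at 0), a tight junction gene, Kdr (2418 ± 67.2 against 0.207 ± 0.358, log2 difference 11.01 ± 0.57), the main VEGF receptor gene, and Cdh5 (3259 ± 222 against 0.910 ± 0.681), the VE-cadherin gene. Of 11 sinusoidal genes, 9 were higher (9 adjusted over the list alone, camera adjusted p = 4.70e-07, adjusted p = 0.121 with an estimated correlation). Examples were the scavenger receptor genes Stab2 (2017 ± 178 against 0.213 ± 0.189, log2 difference 10.71 ± 0.28) and Mrc1 (1286 ± 164 against 1.03 ± 0.234), the adhesion gene Sele (2000.1 ± 1248 against listed at 0) and the nuclease gene Dnase1l3 (954 ± 118 against listed at 0). Arterial genes were higher for 12 and lower for 1 of 19 (13 adjusted over the list alone, camera adjusted p = 0.00134, adjusted p = 0.574 with an estimated correlation). Among them were the podocalyxin gene Podxl (992 ± 65.6 against 0.597 ± 0.280) and the Notch ligand gene Dll4 (377 ± 40.6 against listed at 0). A pair of genes on the smooth muscle and pericyte list, Kcnj8 (1087 ± 113 against 7.97 ± 1.82, log2 difference 6.93 ± 0.18) and Abcc9 (1398 ± 189 against 65.5 ± 4.64), subunits of one potassium channel, was higher in endothelium as well. That list had 3 higher and 4 lower of 14, a mean of 0.13 and a median of -0.03 that turned to 0.13 under quantile normalization (7 adjusted over the list alone, camera adjusted p = 0.768).

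Stroma in vivo led in 13 of 13 osteoblast genes (13 adjusted over the list alone, camera adjusted p = 4.74e-09, adjusted p = 0.101 with an estimated correlation). Examples were the osteocalcin gene Bglap (45.2 ± 26.9 against 26379 ± 6000.3, log2 difference -9.38 ± 0.77), which shares reads with its near copy Bglap2, and Spp1 (55.4 ± 26.8 against 18536 ± 2996). Lepr-positive stroma genes were lower in endothelium for 11 of 13 (12 adjusted over the list alone, camera adjusted p = 1.67e-05, adjusted p = 0.0889 with an estimated correlation). Examples were the adiponectin gene Adipoq (21.8 ± 10.6 against 2698 ± 204), the chemokine gene Cxcl14 (18.8 ± 8.82 against 4597 ± 427) and the BMP antagonist gene Grem1 (5.28 ± 3.63 against 719 ± 150.1, log2 difference -6.97 ± 0.45). Of 23 matrix genes, 21 were lower in endothelium (21 adjusted over the list alone, camera adjusted p = 4.80e-11, adjusted p = 0.121 with an estimated correlation). Type I collagen Col1a1 (54.1 ± 33.1 against 35922 ± 6934, log2 difference -9.48 ± 0.39) and decorin Dcn (7.30 ± 3.71 against 3004 ± 423) were examples. The cartilage collagen gene Col2a1 (1.87 ± 1.81 against 5319 ± 1986, log2 difference -11.05 ± 1.06) followed. Cell cycle genes were lower for 22 of 25 (24 adjusted over the list alone, camera adjusted p = 5.05e-07, adjusted p = 0.577 with an estimated correlation). Members included the proliferation marker Mki67 (16.6 ± 4.60 against 82.4 ± 8.65) and Rrm2 (29.1 ± 9.29 against 203 ± 18.7), a nucleotide reductase gene. The adipocyte list split, with the fatty acid transport genes Fabp4 (28930.3 ± 2869 against 119.7 ± 23.2, log2 difference 7.92 ± 1.60) and Cd36 (3139 ± 398 against 171 ± 32.9) higher in endothelium, which also expresses both, and its median of -0.65 opposed its mean of 0.93 (6 adjusted over the list alone, camera adjusted p = 0.896).

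Blood cell transcripts moved with the stromal libraries in vivo. Erythroid genes were lower in endothelium for 13 of 15 (14 adjusted over the list alone, camera adjusted p = 4.66e-08, adjusted p = 0.121 with an estimated correlation). Among them were the globin gene Hba-a1 (418 ± 175 against 18339 ± 2136, log2 difference -5.54 ± 0.26), one of several near copies that share reads, and the band 3 gene Slc4a1 (16.2 ± 7.32 against 834 ± 160.1). Granulocyte genes were lower for 12 and higher for 4 of 18 (16 adjusted over the list alone, camera adjusted p = 0.00904, adjusted p = 0.502 with an estimated correlation). The alarmin gene S100a8 (33.4 ± 26.9 against 827 ± 393) and the neutrophil granule gene Ngp (4.75 ± 8.23 against 243 ± 112) were lower. Megakaryocyte genes leaned to endothelium, 7 higher and 1 lower of 12 (8 adjusted over the list alone, camera adjusted p = 0.231), and so did 3 of 6 lymphoid genes (3 adjusted over the list alone, camera adjusted p = 0.144). Examples were the T cell kinase gene Lck (41.6 ± 7.62 against 1.51 ± 0.146) and the class II chain gene Cd74 (46.2 ± 9.34 against 4.83 ± 1.33). Of 18 pan-hematopoietic genes, 3 were higher and 7 lower, with a median of -0.46 that turned to 0.04 under quantile normalization (12 adjusted over the list alone, camera adjusted p = 0.322). In all, 7343 of 14904 genes differed, 3733 higher and 3610 lower in endothelium. This fit, and each SE above, shares its spread with the cultured libraries, which varied more. The count was 10639 with the spread taken from the 6 libraries in vivo alone, and 10911 with a weight per group. Trimmed-mean scaling shifted the median of all genes by -0.10 and the share of calls higher in endothelium from 50.8% to 42.6%.

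The endothelial minus stromal differences in culture and in vivo correlated across 14904 genes with Pearson r 0.504 and Spearman rho 0.418, where genes are not independent replicates. Higher in endothelium in both settings were 1549 genes, against 750.2 if the calls were independent, and lower in both were 1353, against 670.9. Opposite calls were found for 225 genes higher in culture and lower in vivo and 255 the other way.

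**Figure D1:**
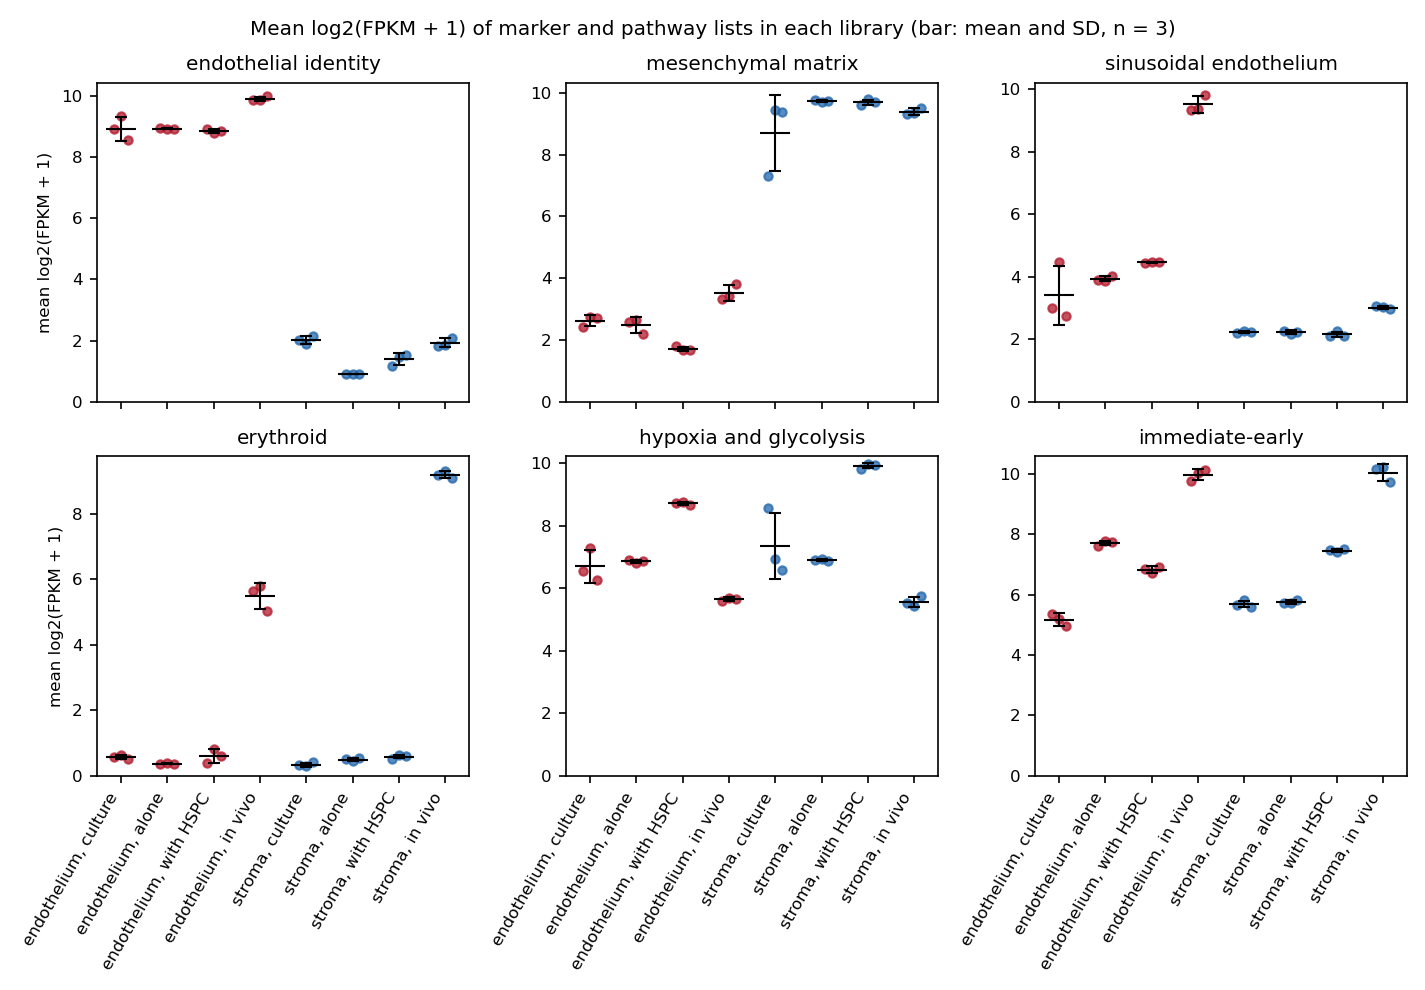
Mean log2(FPKM + 1) over the members of 6 gene lists in each of the 24 libraries, with a point per library and a bar for the mean and SD of each group (n = 3). The sinusoidal list stood highest in endothelium in vivo, the erythroid list in stroma in vivo, and the hypoxia list in stroma with HSPC.

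Endothelial cells in vivo differed from cultured ones by sinusoidal, immediate-early and blood cell transcripts. A total of 11 of 11 sinusoidal genes rose (11 adjusted over the list alone, camera adjusted p = 1.68e-08, adjusted p = 0.119 with an estimated correlation). Among them were Darc (2612 ± 542 against listed at 0), a chemokine receptor gene of venules, the scavenger receptor genes Stab2 (2017 ± 178 against 0.753 ± 0.787, log2 difference 10.25 ± 0.28) and Mrc1 (1286 ± 164 against 0.463 ± 0.585), and Dnase1l3 (954 ± 118 against listed at 0). The arterial genes Gja5 (45.9 ± 4.05 against 3317 ± 2564, log2 difference -5.47 ± 0.95), Gja4 (99.8 ± 12.8 against 2377 ± 2092), Bmx (9.57 ± 1.42 against 288 ± 238) and Jag1 (152 ± 5.74 against 573 ± 329, log2 difference -1.67 ± 0.54), a Notch ligand gene, fell. Over the list, cultured replicate 2 had a mean of 6.06 (6.065), below the 7.14 to 7.30 in vivo, and replicates 1 and 3 had 8.81 and 8.57. On that list 1 rose and 4 fell of 19, and its median of -0.13 turned to 0.09 under trimmed-mean scaling (5 adjusted over the list alone, camera adjusted p = 0.927). Endothelial identity genes rose for 10 and fell for 3 of 26 (13 adjusted over the list alone, camera adjusted p = 0.114). The tight junction gene Cldn5 (2642 ± 275 against 58.7 ± 49.95, log2 difference 6.34 ± 0.89) and Plvap (4930 ± 738 against 345 ± 403), the gene of fenestral diaphragms, were higher. Adipocyte list genes rose for 7 of 9 (8 adjusted over the list alone, camera adjusted p = 0.00226, adjusted p = 0.368 with an estimated correlation), led by Cd36 (3139 ± 398 against 0.443 ± 0.393, log2 difference 11.12 ± 1.34) and Fabp4 (28930.3 ± 2869 against 713 ± 1161), which capillary endothelium also expresses.

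Immediate-early genes rose for 22 of 22 (22 adjusted over the list alone, camera adjusted p = 9.98e-14, adjusted p = 0.0678 with an estimated correlation), with the AP-1 genes Fos (7442 ± 2589 against 6.22 ± 0.227, log2 difference 9.95 ± 0.25) and Fosb (1343 ± 344 against 1.69 ± 0.759) and with Egr1 (3154 ± 783 against 12.2 ± 3.92). Cell cycle genes fell for 25 of 25 (25 adjusted over the list alone, camera adjusted p = 4.23e-11, adjusted p = 0.259 with an estimated correlation). The topoisomerase gene Top2a (24.7 ± 4.91 against 443 ± 248, log2 difference -3.99 ± 0.35) and the kinase gene Cdk1 (16.9 ± 2.68 against 278 ± 40.8) were examples. Cdkn2a (1.47 ± 1.28 against 286 ± 109.8, log2 difference -6.96 ± 0.54), a cell cycle inhibitor gene that builds up in cultured cells, fell as well. Cholesterol synthesis genes fell for 12 of 20 (14 adjusted over the list alone, camera adjusted p = 0.00281, adjusted p = 0.487 with an estimated correlation). The squalene epoxidase gene Sqle (12.2 ± 0.626 against 86.4 ± 36.3) was an example. Interferon response genes rose for 14 of 24 (15 adjusted over the list alone, camera adjusted p = 3.49e-05, adjusted p = 0.171 with an estimated correlation). The viperin gene Rsad2 (162 ± 9.66 against 8.68 ± 2.004) was an example. NF-kB and cytokine response genes rose for 14 and fell for 2 of 21 (16 adjusted over the list alone, camera adjusted p = 0.00314, adjusted p = 0.292 with an estimated correlation). The adhesion gene Vcam1 (4111 ± 670.5 against 99.2 ± 56.6, log2 difference 5.58 ± 0.51) was higher and Ptgs2 (0.477 ± 0.420 against 99.4 ± 50.1), the inducible cyclooxygenase gene, lower. FoxO targets rose for 6 and fell for 1 of 14 (7 adjusted over the list alone, camera adjusted p = 0.00655, adjusted p = 0.259 with an estimated correlation). The thioredoxin inhibitor gene Txnip (5560.3 ± 916 against 967 ± 88.1, log2 difference 2.51 ± 0.31) was an example.

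Genes on the lists of other cell types rose in the same libraries. They comprised 14 of 15 erythroid genes (14 adjusted over the list alone, camera adjusted p = 4.23e-11, adjusted p = 0.119 with an estimated correlation) and 11 of 18 granulocyte genes (11 adjusted over the list alone, camera adjusted p = 4.31e-05, adjusted p = 0.171 with an estimated correlation). Examples were the globin gene Hba-a1 (418 ± 175 against listed at 0) and the myeloperoxidase gene Mpo (104 ± 45.3 against listed at 0). They also held 15 of 18 pan-hematopoietic genes (15 adjusted over the list alone, camera adjusted p = 5.14e-08, adjusted p = 0.123 with an estimated correlation) and 8 of 12 megakaryocyte genes (9 adjusted over the list alone, camera adjusted p = 0.00122, adjusted p = 0.259 with an estimated correlation). The platelet chemokine gene Ppbp (169.5 ± 133 against listed at 0) was one. Smooth muscle and pericyte genes rose for 10 of 14 (10 adjusted over the list alone, camera adjusted p = 6.40e-05, adjusted p = 0.185 with an estimated correlation). Lepr-positive stroma genes rose for 8 and fell for 1 of 13 (9 adjusted over the list alone, camera adjusted p = 0.0114, adjusted p = 0.204 with an estimated correlation). Lymphoid genes rose for 4 of 6 (4 adjusted over the list alone, camera adjusted p = 0.0192, adjusted p = 0.258 with an estimated correlation), and under trimmed-mean scaling that list had adjusted p = 0.0519 (0.0101 to 0.258 over the alternatives). Osteoblast genes rose for 5 of 13 (5 adjusted over the list alone, camera adjusted p = 0.0216, adjusted p = 0.368 with an estimated correlation), with the bone sialoprotein gene Ibsp (66.2 ± 36.5 against listed at 0). Matrix genes rose for 12 and fell for 2 of 23 (15 adjusted over the list alone, camera adjusted p = 0.0264, adjusted p = 0.487 with an estimated correlation). Trimmed-mean scaling left adjusted p = 0.0519 (0.0101 to 0.368 over the alternatives) and 0.0915 (0.00292 to 0.487 over the alternatives) for these lists. In all, 7951 of 14904 genes changed, 3511 up and 4440 down. The share of calls higher in vivo was 44.2%, and 55.2% under trimmed-mean scaling.

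Stroma in vivo carried far higher levels of marrow niche, bone and blood cell transcripts than cultured stroma. Lepr-positive stroma genes rose for 10 of 13 (10 adjusted over the list alone, camera adjusted p = 1.11e-05, adjusted p = 0.0440 with an estimated correlation). Examples were the niche chemokine gene Cxcl12 (75167 ± 5228 against 638 ± 423, log2 difference 7.25 ± 0.92), the leptin receptor gene Lepr (2586 ± 176 against 5.11 ± 8.85, log2 difference 9.99 ± 1.06) and the growth factor binding gene Igfbp5 (6887 ± 584 against 35.3 ± 30.2). Osteoblast genes rose for 11 of 13 (12 adjusted over the list alone, camera adjusted p = 7.79e-07, adjusted p = 0.0805 with an estimated correlation). The bone sialoprotein gene Ibsp (10343 ± 1164 against listed at 0) and the osteocalcin gene Bglap (26379 ± 6000.3 against 4.71 ± 4.43, log2 difference 12.67 ± 0.77) were among them. HSC niche factors rose for 13 and fell for 5 of 28 (19 adjusted over the list alone, camera adjusted p = 0.0232, adjusted p = 0.267 with an estimated correlation). The lymphoid cytokine gene Il7 (162 ± 14.1 against 8.79 ± 8.64, log2 difference 4.40 ± 0.54) and Bmp4 (216 ± 18.4 against 18.9 ± 29.2) were higher, and for the list under trimmed-mean scaling the adjusted p was 0.111 (0.0185 to 0.267 over the alternatives). Notch targets rose for 6 of 7 (7 adjusted over the list alone, camera adjusted p = 0.00316, adjusted p = 0.0805 with an estimated correlation). Members included the effector gene Heyl (244 ± 81.4 against listed at 0) and the receptor gene Notch3 (401 ± 47.5 against 23.1 ± 19.2, log2 difference 4.83 ± 0.85). Matrix genes went both ways, 5 up and 4 down of 23 (9 adjusted over the list alone, camera adjusted p = 0.382). The decorin gene Dcn (3004 ± 423 against 22.4 ± 19.2, log2 difference 7.58 ± 0.71) was higher and the fibroblast surface gene Thy1 (8.87 ± 1.41 against 1315 ± 1096, log2 difference -6.42 ± 0.73) lower. Of the smooth muscle and pericyte genes 7 rose and 3 fell of 14 (11 adjusted over the list alone, camera adjusted p = 0.0232, adjusted p = 0.336 with an estimated correlation). The smooth muscle actin gene Acta2 (24.04 ± 7.90 against 1087 ± 332) fell. Under trimmed-mean scaling that list gave adjusted p = 0.0964 (0.0270 to 0.336 over the alternatives).

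Erythroid genes rose for 15 of 15 (15 adjusted over the list alone, camera adjusted p = 1.29e-14, adjusted p = 0.0440 with an estimated correlation), led by the globin genes Hbb-b1 (19696 ± 2424 against listed at 0) and Hba-a1 (18339 ± 2136 against listed at 0), whose near copies share reads. Granulocyte genes rose for 17 of 18 (17 adjusted over the list alone, camera adjusted p = 8.49e-10, adjusted p = 0.0440 with an estimated correlation). The alarmin gene S100a8 (827 ± 393 against listed at 0) and the granule gene Ngp (243 ± 112 against listed at 0) were examples. Immediate-early genes rose for 20 of 22 (20 adjusted over the list alone, camera adjusted p = 4.01e-12, adjusted p = 0.0440 with an estimated correlation). The AP-1 gene Fos (9142 ± 1333 against 5.87 ± 1.69, log2 difference 10.40 ± 0.25) and the cytokine feedback gene Socs3 (3843 ± 1628 against 36.0 ± 5.25) were examples. Interferon response genes rose for 20 and fell for 1 of 24 (22 adjusted over the list alone, camera adjusted p = 1.35e-06, adjusted p = 0.0805 with an estimated correlation). Examples were the viperin gene Rsad2 (338 ± 53.4 against 1.15 ± 1.27) and the chemokine gene Cxcl10 (156 ± 42.8 against 2.84 ± 3.20, log2 difference 5.74 ± 0.64). Cholesterol synthesis genes fell for 20 of 20 (20 adjusted over the list alone, camera adjusted p = 1.35e-06, adjusted p = 0.336 with an estimated correlation). Hypoxia and glycolysis genes fell for 14 and rose for 2 of 20 (17 adjusted over the list alone, camera adjusted p = 0.00428, adjusted p = 0.479 with an estimated correlation). The glycolysis gene Pgk1 (24.6 ± 2.52 against 488 ± 546) was an example. Cell cycle genes fell for 15 of 25 (16 adjusted over the list alone, camera adjusted p = 0.00273, adjusted p = 0.554 with an estimated correlation). The fetal chromatin gene Hmga2 (0.580 ± 0.0173 against 1136 ± 182, log2 difference -9.48 ± 0.36) was among the largest falls. In all, 8256 of 14904 genes changed, 3575 up and 4681 down. Trimmed-mean scaling shifted the median of all genes by 0.22 and the share of calls higher in vivo from 43.3% to 57.9%.

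From culture to in vivo, sinusoidal genes gained more in endothelium, and bone and erythroid genes in stroma. The endothelial minus stromal change was 10.19 ± 0.40 for Stab2, 12.98 ± 0.45 for the endothelial lipase gene Lipg and 10.42 ± 2.27 for Fabp4. It was -8.10 ± 1.49 for the receptor gene Lepr, -6.91 ± 1.30 for Cxcl12, -7.82 ± 0.67 for Bmx and 8.38 ± 1.03 for Thy1. The median difference over the sinusoidal list was 6.70 (camera adjusted p = 2.59e-07, adjusted p = 0.231 with an estimated correlation), over the osteoblast list -3.85 (camera adjusted p = 6.74e-05, adjusted p = 0.320 with an estimated correlation) and over the erythroid list -3.84 (camera adjusted p = 7.81e-09, adjusted p = 0.231 with an estimated correlation). In all, the change differed between the cell types for 5000 of 14904 genes, 2450 with the higher change in endothelium and 2550 in stroma. Of these, 615 changed in opposite directions with both calls. A fit of all 8 groups called 7654 genes.

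**Figure D2:**
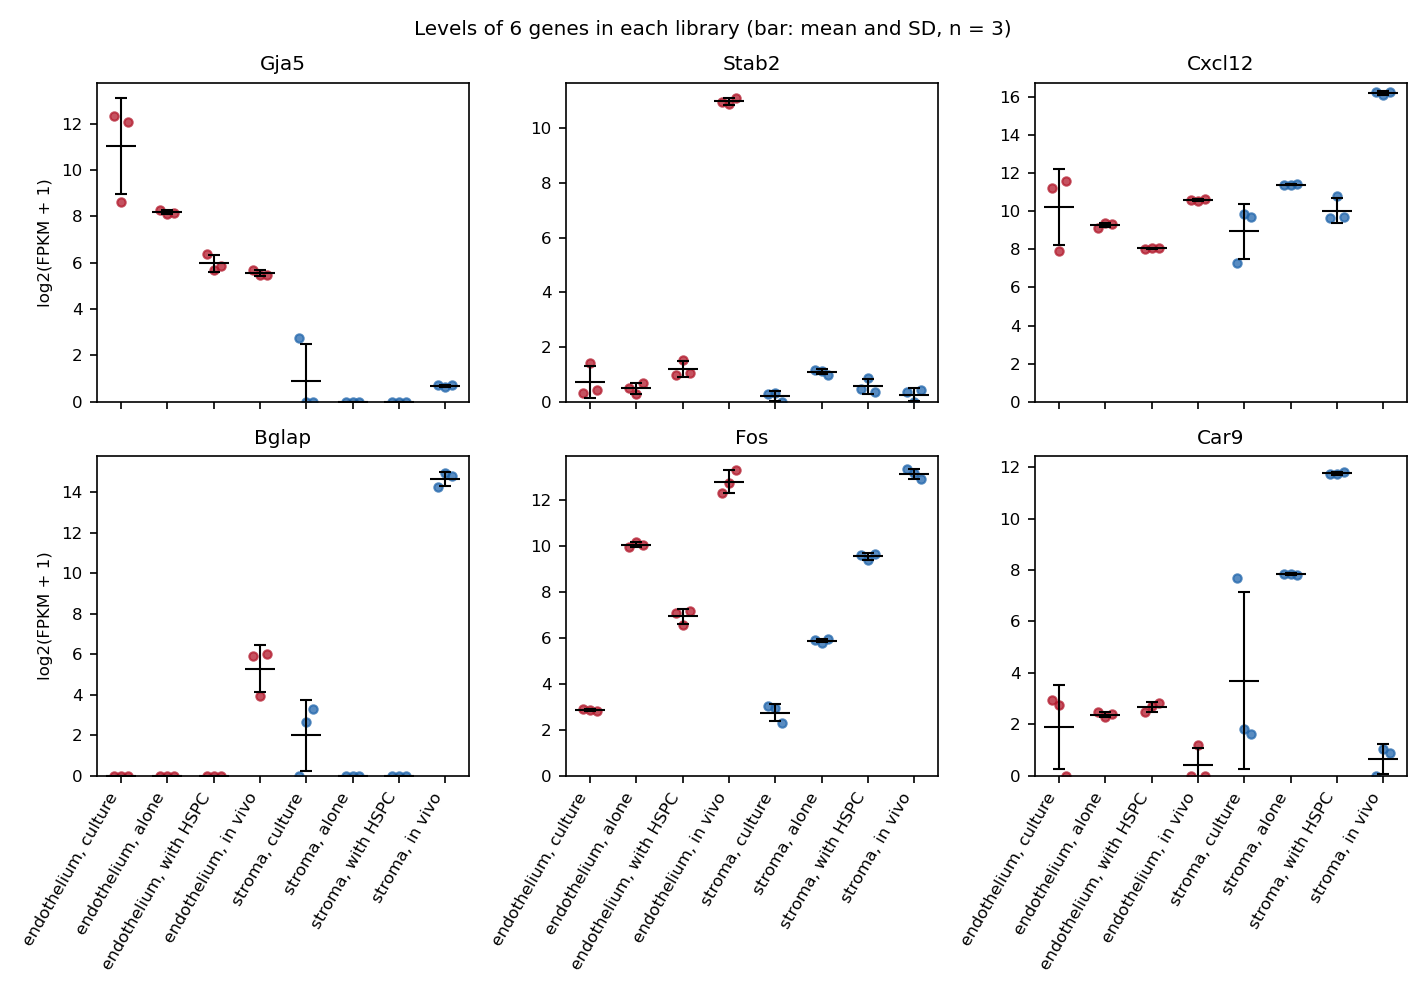
Log2(FPKM + 1) of 6 genes in each of the 24 libraries, with a point per library and a bar for the mean and SD of each group (n = 3). Mean Cxcl12 was 75167 FPKM in stroma in vivo, mean Stab2 2017 in endothelium in vivo, and mean Car9 3479 in stroma with HSPC.

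In endothelial libraries with HSPC, genes of hypoxia and glycolysis and of cholesterol synthesis were higher and arterial genes lower than alone. A response to HSPC means a difference between libraries with HSPC and alone here, whatever its source. A total of 20 of 20 hypoxia and glycolysis genes rose (20 adjusted over the list alone, camera adjusted p = 3.71e-16, adjusted p = 0.0262 with an estimated correlation). Examples were the HIF targets Ankrd37 (247 ± 27.4 against 19.1 ± 1.39, log2 difference 3.62 ± 0.09), Bnip3 (563 ± 42.6 against 54.5 ± 7.62, log2 difference 3.35 ± 0.10) and Hk2 (60.2 ± 3.08 against 6.44 ± 0.342), the gene of the first enzyme of glycolysis. Cholesterol synthesis genes rose for 18 and fell for 1 of 19 (19 adjusted over the list alone, camera adjusted p = 9.91e-07, adjusted p = 0.279 with an estimated correlation). Among them were the enzyme genes Fdft1 (347 ± 4.52 against 151 ± 7.03, log2 difference 1.20 ± 0.07) and Mvd (156 ± 2.03 against 72.0 ± 7.11). Arterial genes fell for 12 and rose for 4 of 19 (16 adjusted over the list alone, camera adjusted p = 0.0001502, adjusted p = 0.274 with an estimated correlation). The gap junction genes Gja4 (7.40 ± 3.44 against 155 ± 15.1, log2 difference -4.29 ± 0.21) and Gja5 (63.8 ± 17.0 against 290.1 ± 19.3), the kinase gene Bmx (10.4 ± 2.61 against 58.5 ± 5.91) and the Notch ligand gene Jag1 (45.5 ± 1.798 against 178 ± 5.19, log2 difference -1.94 ± 0.04) were lower. Sinusoidal genes rose for 7 of 9 (7 adjusted over the list alone, camera adjusted p = 0.00431, adjusted p = 0.228 with an estimated correlation). The scavenger receptor gene Stab1 (802 ± 17.9 against 347 ± 33.5, log2 difference 1.21 ± 0.07) and the VEGF-C receptor gene Flt4 (197 ± 5.07 against 89.3 ± 1.14) were examples. Endothelial identity genes went both ways, 6 up and 7 down of 26 (13 adjusted over the list alone, camera adjusted p = 0.386). The von Willebrand factor gene Vwf (51.1 ± 8.43 against 216 ± 11.5, log2 difference -2.06 ± 0.15) was lower and Plvap (67.9 ± 3.29 against 24.6 ± 1.62) higher.

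Immediate-early genes fell for 11 and rose for 2 of 22 (16 adjusted over the list alone, camera adjusted p = 3.41e-05, adjusted p = 0.274 with an estimated correlation). Examples were the AP-1 genes Fosb (22.5 ± 6.80 against 416 ± 49.5, log2 difference -4.18 ± 0.18) and Fos (124 ± 26.4 against 1074 ± 72.0). Matrix genes fell for 12 and rose for 1 of 23 (13 adjusted over the list alone, camera adjusted p = 5.69e-05, adjusted p = 0.208 with an estimated correlation). The fibrillin gene Fbn1 (8.60 ± 0.691 against 70.6 ± 6.29) was one of them. The elastin gene Eln (83.8 ± 17.0 against 1558 ± 116, log2 difference -4.22 ± 0.21) and Tgfbi (5.93 ± 1.37 against 97.4 ± 3.75), a TGF-beta target, fell too. Cell cycle genes fell for 18 of 25 (22 adjusted over the list alone, camera adjusted p = 1.06e-05, adjusted p = 0.334 with an estimated correlation). The change was small, as in the regulator Foxm1 (38.3 ± 1.04 against 61.1 ± 3.81, log2 difference -0.66 ± 0.07). NF-kB and cytokine response genes rose for 10 of 19 (10 adjusted over the list alone, camera adjusted p = 0.0402, adjusted p = 0.618 with an estimated correlation). The cytokine genes Ccl7 (395 ± 14.4 against 42.4 ± 6.83, log2 difference 3.20 ± 0.41) and Il6 (14.4 ± 0.594 against 4 ± 0.413) rose, though for the list a pseudocount of 0.1 left adjusted p = 0.0540 (0.0299 to 0.618 over the alternatives). Among HSC niche factors 7 rose and 11 fell of 28 (19 adjusted over the list alone, camera adjusted p = 0.125). The growth factor gene Igf2 (75.6 ± 8.76 against 402 ± 23.9, log2 difference -2.40 ± 0.22) and the niche chemokine gene Cxcl12 (264 ± 7.30 against 619 ± 53.5) were lower. FoxO targets went both ways, 7 up and 3 down of 14 (10 adjusted over the list alone, camera adjusted p = 0.458). The cyclin G2 gene Ccng2 (242 ± 10.8 against 67.7 ± 5.10) was higher.

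Blood cell transcripts, listed at or near 0 alone, moved with HSPC beside these groups. Granulocyte genes rose for 15 and fell for 1 of 16 (16 adjusted over the list alone, camera adjusted p = 6.46e-12, adjusted p = 0.0217 with an estimated correlation). The alarmin gene S100a8 (513 ± 65.0 against listed at 0) and the granule enzyme genes Elane (383 ± 53.9 against listed at 0) and Mpo (194 ± 35.9 against listed at 0) were examples. A total of 18 of 18 pan-hematopoietic genes rose (18 adjusted over the list alone, camera adjusted p = 2.52e-13, adjusted p = 0.0502 with an estimated correlation). Monocyte and macrophage genes rose for 6 of 6 (6 adjusted over the list alone, camera adjusted p = 3.41e-05, adjusted p = 0.0217 with an estimated correlation). The adaptor gene Tyrobp (54.2 ± 8.98 against listed at 0) and the chemokine receptor gene Ccr2 (10.1 ± 2.60 against listed at 0) were examples. Megakaryocyte genes rose for 6 and fell for 1 of 8 (7 adjusted over the list alone, camera adjusted p = 0.0248, adjusted p = 0.327 with an estimated correlation). In all, 6813 of 14017 genes changed, 3962 up and 2851 down, of which 1018 moved at least 2-fold. With all 8 groups in the fit the count was 1852. The share of calls higher with HSPC was 58.2%, and 45.4% under quantile normalization.

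In stroma, HSPC came with a rise of hypoxia genes, a rise of immediate-early genes and a fall of cell cycle and interferon genes. A total of 20 of 20 hypoxia and glycolysis genes rose (20 adjusted over the list alone, camera adjusted p = 8.62e-20, adjusted p = 0.0216 with an estimated correlation). Among them were Egln3 (712 ± 123 against 12.7 ± 1.46, log2 difference 5.70 ± 0.11), the HIF prolyl hydroxylase gene, the oxidase gene Ero1l (4648 ± 862 against 125 ± 6.19, log2 difference 5.19 ± 0.11), the carbonic anhydrase gene Car9 (3479 ± 126 against 228 ± 5.22) and the mitophagy gene Bnip3 (2152 ± 195 against 136 ± 7.12). Immediate-early genes rose for 17 and fell for 3 of 22 (20 adjusted over the list alone, camera adjusted p = 6.02e-08, adjusted p = 0.252 with an estimated correlation). Examples were the AP-1 genes Fosb (234 ± 31.4 against 8.61 ± 0.715, log2 difference 4.61 ± 0.18) and Fos (755 ± 71.5 against 57.9 ± 3.01) and the stress factor gene Atf3 (144 ± 30.5 against 14.7 ± 1.94). Cell cycle genes fell for 24 of 25 (24 adjusted over the list alone, camera adjusted p = 2.86e-09, adjusted p = 0.317 with an estimated correlation). Members included the replication gene Mcm5 (7.50 ± 1.496 against 30.7 ± 4.40, log2 difference -1.91 ± 0.14) and the proliferation marker Mki67 (6.45 ± 1.90 against 24.1 ± 2.27). Interferon response genes fell for 19 and rose for 2 of 23 (21 adjusted over the list alone, camera adjusted p = 0.00176, adjusted p = 0.606 with an estimated correlation). The induced gene Ifit3 (11.2 ± 3.42 against 82.1 ± 35.6, log2 difference -2.73 ± 0.26) and the chemokine gene Cxcl10 (4.80 ± 1.81 against 27.9 ± 6.86) were lower and the nuclease gene Isg20 (114 ± 10.6 against 12.9 ± 1.66) higher. Cholesterol synthesis genes fell for 15 of 19 (15 adjusted over the list alone, camera adjusted p = 8.16e-04, adjusted p = 0.559 with an estimated correlation). The enzyme genes Acat2 (32.2 ± 6.77 against 71.7 ± 6.79, log2 difference -1.14 ± 0.12) and Dhcr7 (23.9 ± 0.787 against 45.7 ± 3.58) were examples.

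Niche factors went both ways in stroma, 10 up and 10 down of 28, with a median of 0.04 and a mean of -0.11 (20 adjusted over the list alone, camera adjusted p = 0.802). Lower were the niche chemokine gene Cxcl12 (1129 ± 565 against 2696 ± 10.7, log2 difference -1.36 ± 0.24), the Tie2 ligand gene Angpt1 (121 ± 22.1 against 484 ± 7.75, log2 difference -2.00 ± 0.18), the pleiotrophin gene Ptn (489 ± 168 against 2139.8 ± 96.4) and the adhesion gene Vcam1 (224 ± 72.5 against 757 ± 17.0). Matrix genes rose for 6 and fell for 8 of 23, with a median of 0.11 that quantile normalization took to 0, a mean of -0.03 and a test pointing up (14 adjusted over the list alone, camera adjusted p = 0.802). The fibronectin gene Fn1 (12509 ± 986 against 4662 ± 182, log2 difference 1.42 ± 0.08) and the crosslinking enzyme gene Lox (7475 ± 435 against 2975 ± 20.4) rose, and the proteoglycan gene Lum (142 ± 29.7 against 699 ± 3.78) fell. Smooth muscle and pericyte genes fell for 5 and rose for 2 of 7 (7 adjusted over the list alone, camera adjusted p = 0.269). The smooth muscle actin gene Acta2 (134 ± 52.0 against 622 ± 73.6, log2 difference -2.26 ± 0.21) was lower and the receptor gene Notch3 (30.4 ± 13.2 against 3.08 ± 0.0513) higher. H19 (309 ± 87.3 against 2.38 ± 0.105, log2 difference 6.48 ± 0.23), an imprinted noncoding transcript, rose, and Nppc (listed at 0 against 30.5 ± 4.27), a natriuretic peptide gene, fell.

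Granulocyte genes rose in these libraries too, for 14 of 16 (14 adjusted over the list alone, camera adjusted p = 2.49e-11, adjusted p = 0.0216 with an estimated correlation). Examples were the granule and alarmin genes S100a8 (240 ± 47.9 against listed at 0), Elane (108 ± 13.8 against listed at 0) and Mpo (62.0 ± 0.997 against listed at 0). Pan-hematopoietic genes rose for 17 of 18 (17 adjusted over the list alone, camera adjusted p = 2.48e-09, adjusted p = 0.167 with an estimated correlation). The adaptor gene Tyrobp (11.9 ± 1.58 against listed at 0) was an example. Monocyte and macrophage genes rose for 2 and fell for 3 of 6, with a median of -0.09 but a mean of 0.20 (5 adjusted over the list alone, camera adjusted p = 0.802). Some endothelial genes rose with HSPC in stroma, 10 of 26 (8 adjusted over the list alone, camera adjusted p = 0.0158, adjusted p = 0.481 with an estimated correlation), among them Plvap (55.5 ± 2.68 against 3.33 ± 0.222, log2 difference 3.71 ± 0.07) and Pecam1 (1.59 ± 0.599 against listed at 0). In all, 8551 of 14017 genes changed, 3588 up and 4963 down, of which 1553 moved at least 2-fold. With all 8 groups in the fit the count was 3591.

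Of 22 immediate-early genes, 11 fell and 2 rose with HSPC in endothelium, and 17 rose and 3 fell in stroma. With an estimated correlation the list had adjusted p = 0.274 and 0.252. The endothelial minus stromal response was -8.79 ± 0.25 for the AP-1 gene Fosb, -6.80 ± 0.19 for Fos, -5.53 ± 0.17 for Tgfbi and -7.47 ± 0.32 for H19. It was -3.63 ± 0.12 for Car9, -4.29 ± 0.30 for Gja4, 1.79 ± 0.10 for Mvd, 2.93 ± 0.26 for Angpt1 and 4.40 ± 0.11 for Nppc. Over lists, the median difference was -2.46 (camera adjusted p = 2.36e-14, adjusted p = 0.0754 with an estimated correlation) for immediate-early genes, 1.26 (camera adjusted p = 2.03e-07, adjusted p = 0.301 with an estimated correlation) for cholesterol synthesis and -0.82 (camera adjusted p = 2.68e-11, adjusted p = 0.0754 with an estimated correlation) for hypoxia and glycolysis. The blood cell lists differed as well, by 1.93 (camera adjusted p = 0.00196, adjusted p = 0.0754 with an estimated correlation) for monocyte and macrophage genes and 1.52 (camera adjusted p = 0.00120, adjusted p = 0.301 with an estimated correlation) for pan-hematopoietic genes. In all, the response differed for 7996 of 14017 genes, 5045 with the higher change in endothelium and 2951 in stroma. The share of calls with the higher change in endothelium was 63.1%, 55.9% under trimmed-mean scaling and 54.3% under quantile normalization. Of the called genes, 1583 moved in opposite directions with both calls. With all 8 groups in the fit the count was 2276.

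The responses to HSPC of endothelium and stroma correlated across 14017 genes with Pearson r 0.330 and Spearman rho 0.218, where genes are not independent replicates. Up in both were 1511 genes, against 1014 (1014.2) if the calls were independent, and down in both were 1338, against 1009.5. A further 1000 genes rose in endothelium and fell in stroma, and 583 did the reverse.

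**Figure D3:**
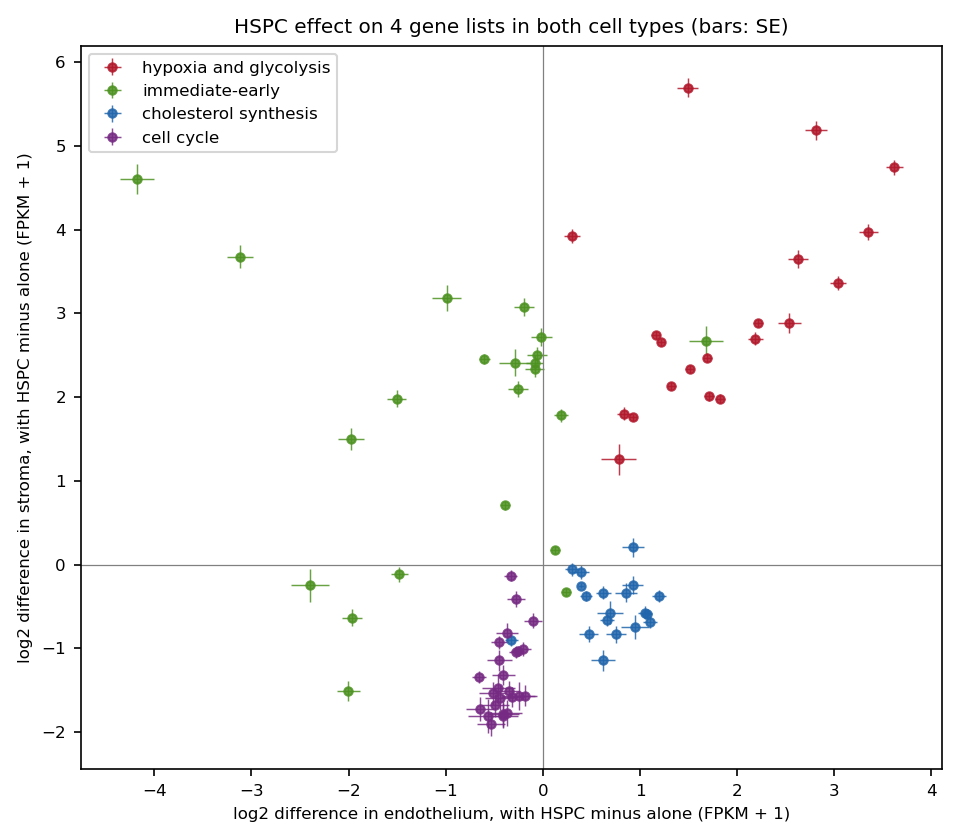
Log2 difference with HSPC minus alone of each gene on 4 lists, endothelium on the horizontal and stroma on the vertical axis, with SE bars. All 20 hypoxia and glycolysis genes lie above 0 on both axes, cell cycle genes lie mostly below 0 on both, and cholesterol synthesis and immediate-early genes lie mostly on opposite sides of 0 in the 2 cell types.

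In the second culture series endothelium and stroma kept their identity genes, without and with HSPC. Endothelial identity genes were higher alone for 26 of 26 (26 adjusted over the list alone, camera adjusted p = 1.41e-12, adjusted p = 0.0740 with an estimated correlation) and with HSPC for 26 of 26 (26 adjusted over the list alone, camera adjusted p = 1.22e-10, adjusted p = 0.123 with an estimated correlation). The receptor gene Tie1 (1825 ± 3.36 against listed at 0) was one alone, and the junction gene Pecam1 (6491 ± 104 against 1.59 ± 0.599, log2 difference 11.32 ± 0.13) with HSPC. Matrix genes were lower alone for 23 of 23 (23 adjusted over the list alone, camera adjusted p = 2.58e-10, adjusted p = 0.0740 with an estimated correlation) and with HSPC for 23 of 23 (23 adjusted over the list alone, camera adjusted p = 2.99e-11, adjusted p = 0.0997 with an estimated correlation). The type I collagen gene Col1a1 (5.05 ± 3.97 against 26466 ± 2117, log2 difference -12.46 ± 0.52) was one alone, and Postn (0.180 ± 0.312 against 5856 ± 259.6, log2 difference -12.31 ± 0.22), the periostin gene of fibroblasts, with HSPC. Arterial genes were higher for 19 of 19 alone (19 adjusted over the list alone, camera adjusted p = 5.23e-08, adjusted p = 0.142 with an estimated correlation). Among them were the gap junction gene Gja5 (290.1 ± 19.3 against listed at 0) and Podxl (832 ± 37.5 against listed at 0), the podocalyxin gene.

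Pathway genes also separated these cultures. Cholesterol synthesis genes were higher for 19 of 19 alone (19 adjusted over the list alone, camera adjusted p = 8.64e-06, adjusted p = 0.340 with an estimated correlation) and for 19 of 19 with HSPC (19 adjusted over the list alone, camera adjusted p = 7.18e-07, adjusted p = 0.302 with an estimated correlation). The sterol carrier gene Stard4 (299 ± 5.72 against 28.6 ± 2.43, log2 difference 3.34 ± 0.06) was one alone, and Idi1 (414 ± 17.6 against 36.0 ± 7.17, log2 difference 3.51 ± 0.13), an isomerase gene of the pathway, with HSPC. Cell cycle genes were higher for 24 of 25 alone (24 adjusted over the list alone, camera adjusted p = 3.93e-05, adjusted p = 0.406 with an estimated correlation) and for 25 of 25 with HSPC (25 adjusted over the list alone, camera adjusted p = 2.91e-06, adjusted p = 0.302 with an estimated correlation). The survivin gene Birc5 (128 ± 7.47 against 10.8 ± 2.07, log2 difference 3.46 ± 0.14) was among the latter. Hypoxia and glycolysis genes were lower with HSPC for 16 and higher for 4 of 20 (20 adjusted over the list alone, camera adjusted p = 0.00311, adjusted p = 0.302 with an estimated correlation). Alone 11 were higher and 8 lower, with a median of 0.36 and a mean of -0.05 (19 adjusted over the list alone, camera adjusted p = 0.699). The HIF target Car9 (5.44 ± 0.805 against 3479 ± 126, log2 difference -9.09 ± 0.08) was lower with HSPC. Interferon response genes were higher with HSPC for 20 of 23 (22 adjusted over the list alone, camera adjusted p = 0.00274, adjusted p = 0.417 with an estimated correlation). The tetherin gene Bst2 (1737 ± 91.8 against 96.8 ± 15.6) was an example. The niche genes Ptn (listed at 0 against 2139.8 ± 96.4) and Angpt1 (listed at 0 against 484 ± 7.75) were higher in stroma alone, and Igf2 (402 ± 23.9 against 0.297 ± 0.261, log2 difference 8.30 ± 0.22) in endothelium. In all, 11678 of 14017 genes differed alone, 5892 higher and 5786 lower in endothelium, and 11934 with HSPC, 6526 higher and 5408 lower.

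The cultures alone also differed from the first cultures, whose cells, media and dates the labels do not relate to each other. In endothelium, immediate-early genes were higher alone for 18 of 22 (22 adjusted over the list alone, camera adjusted p = 7.54e-17, adjusted p = 0.00578 with an estimated correlation). The transcription factor genes Fos (1074 ± 72.0 against 6.22 ± 0.227, log2 difference 7.22 ± 0.17), Fosb (416 ± 49.5 against 1.69 ± 0.759) and Egr1 (856 ± 44.0 against 12.2 ± 3.92) were examples. Cholesterol synthesis genes were higher for 16 of 20 (18 adjusted over the list alone, camera adjusted p = 3.11e-13, adjusted p = 0.359 with an estimated correlation). The squalene epoxidase gene Sqle (445 ± 11.6 against 86.4 ± 36.3, log2 difference 2.43 ± 0.27) was an example. Cell cycle genes were lower for 16 of 25 (17 adjusted over the list alone, camera adjusted p = 3.32e-07, adjusted p = 0.819 with an estimated correlation). The kinase gene Cdk1 (71.8 ± 7.78 against 278 ± 40.8, log2 difference -1.94 ± 0.26) was an example. TGF-beta and BMP targets were lower for 7 and higher for 1 of 14 (8 adjusted over the list alone, camera adjusted p = 0.00493, adjusted p = 0.0916 with an estimated correlation). The inhibitor genes Id3 (57.2 ± 4.17 against 1395 ± 624, log2 difference -4.50 ± 0.25) and Smad6 (2.89 ± 0.753 against 116 ± 83.1) were lower. The prostaglandin synthase gene Ptgds (774 ± 31.5 against 4.83 ± 5.17, log2 difference 7.64 ± 0.66) was higher and the smooth muscle actin gene Acta2 (0.380 ± 0.0458 against 296 ± 264) lower. In all, 3267 of 14071 genes differed, 1236 up and 2031 down. That count fell to between 1593 and 1671 without one of the 3 libraries of endothelium alone and was 5910 with all 8 groups in the fit. The share of calls higher alone was 37.8%, 53.9% under trimmed-mean scaling, which shifted the median of all genes by 0.11, and 51.3% under quantile normalization.

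In stroma, cell cycle genes were lower alone than in the first cultures for 25 of 25 (25 adjusted over the list alone, camera adjusted p = 5.43e-14, adjusted p = 0.677 with an estimated correlation). The proliferation marker Mki67 (24.1 ± 2.27 against 180.5 ± 57.8, log2 difference -2.81 ± 0.27) was an example. Adipocyte genes were lower for 6 of 6 (6 adjusted over the list alone, camera adjusted p = 0.00451, adjusted p = 0.7496 with an estimated correlation). Among them were Pparg (6.84 ± 0.760 against 135 ± 70.9, log2 difference -3.93 ± 0.85), the master regulator of fat cells, and the adiponectin gene Adipoq (listed at 0 against 132 ± 129). The list mean in cultured stroma was 2.45 in replicate 1 against 7.10 and 6.32 in replicates 2 and 3, and at most 1.19 alone, so most of this fall came from replicates 2 and 3. TGF-beta and BMP targets were lower for 9 of 14 (10 adjusted over the list alone, camera adjusted p = 0.00112, adjusted p = 0.0933 with an estimated correlation). The inhibitor gene Id1 (51.0 ± 5.50 against 553 ± 255, log2 difference -3.33 ± 0.39) and the matricellular gene Ctgf (144 ± 6.53 against 2009.8 ± 1307) were examples. Cholesterol synthesis genes were lower for 11 of 20 (16 adjusted over the list alone, camera adjusted p = 9.92e-04, adjusted p = 0.760 with an estimated correlation). Endothelial identity genes were lower for 14 and higher for 2 of 26 (19 adjusted over the list alone, camera adjusted p = 3.16e-04, adjusted p = 0.331 with an estimated correlation). The junction gene Pecam1 (listed at 0 against 4.56 ± 1.04) was an example. FoxO targets were higher for 6 and lower for 2 of 14 (10 adjusted over the list alone, camera adjusted p = 0.0312, adjusted p = 0.7496 with an estimated correlation). The thioredoxin inhibitor gene Txnip (2538 ± 17.8 against 267 ± 119, log2 difference 3.36 ± 0.29) was higher, and for the list trimmed-mean scaling left adjusted p = 0.0583 (0.0209 to 0.7496 over the alternatives). The matrix genes Lum (699 ± 3.78 against listed at 0), Abi3bp (3852 ± 96.2 against 2.97 ± 3.49, log2 difference 10.27 ± 0.46) and Fmod (962 ± 85.3 against 1.31 ± 0.506) were higher, and the surface gene Thy1 (1.34 ± 0.485 against 1315 ± 1096, log2 difference -8.50 ± 0.74) and the protease inhibitor gene Serpinb2 (listed at 0 against 319.7 ± 264) were lower. In all, 4760 of 14071 genes differed, 2257 up and 2503 down. The share of calls higher alone was 47.4%, 51.5% under trimmed-mean scaling and 53.2% under quantile normalization. That count fell to between 3070 and 3152 without one of the 3 libraries of stroma alone.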

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

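The genes and lists of the next 2 paragraphs were singled out because a test of the difference between endothelium and stroma passed for the same contrast, and Xist and the Y-linked genes because their values had been seen. The tests on blood cell RNA, on culture day or vessel, on carry-over and on sex were chosen after the result was seen, and those on scaling and on splits before. Groups of 3 were too small for a test of single libraries that stand apart.

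The change from culture to in vivo differed between the cell types for 5000 genes. The median difference over list members (endothelium minus stroma) was 6.70 for sinusoidal endothelium, 4.91 for adipocyte, 1.86 for smooth muscle and pericyte and 1.11 for cholesterol synthesis. It was -3.85 for osteoblast, -3.84 for erythroid, -3.24 for granulocyte, -2.94 for Notch targets, -1.86 for cell cycle and -1.49 for Lepr-positive stroma. A pseudocount of 0.1 left adjusted p = 0.185 (0.0399 to 0.485 over the alternatives) for Lepr-positive stroma and 0.0552 (0.0151 to 0.605 over the alternatives) for granulocyte, and trimmed-mean scaling left 0.0620 for the former. With an estimated correlation none of these 10 lists passed. Among genes the difference was 12.98 ± 0.45 for Lipg, 10.42 ± 2.27 for Fabp4, 10.19 ± 0.40 for Stab2, 8.38 ± 1.03 for Thy1, -7.82 ± 0.67 for Bmx, -8.10 ± 1.49 for Lepr and -6.91 ± 1.30 for Cxcl12.

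The response to HSPC differed between the cell types for 7996 genes. The median difference over list members was 1.93 for monocyte and macrophage, 1.52 for pan-hematopoietic, 1.49 for interferon response, 1.26 for cholesterol synthesis, 1.12 for granulocyte, 1.02 for cell cycle and 0.83 for sinusoidal endothelium. It was -2.46 for immediate-early, -1.35 for arterial endothelium, -0.82 for hypoxia and glycolysis, -0.61 for mesenchymal matrix, -0.49 for endothelial identity and -0.42 for Notch targets. A pseudocount of 0.1 left adjusted p = 0.426 (0.0181 to 0.426 over the alternatives) for sinusoidal endothelium, 0.106 (0.0243 to 0.331 over the alternatives) for granulocyte and 0.0693 (0.0418 to 0.301 over the alternatives) for Notch targets. With an estimated correlation none of these 13 lists passed. Among genes the difference was 4.40 ± 0.11 for Nppc, 2.93 ± 0.26 for Angpt1, 1.79 ± 0.10 for Mvd, 1.08 ± 0.06 for Akt1, -3.63 ± 0.12 for Car9, -4.29 ± 0.30 for Gja4, -5.53 ± 0.17 for Tgfbi, -6.80 ± 0.19 for Fos, -7.47 ± 0.32 for H19 and -8.79 ± 0.25 for Fosb.

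Hypoxia and glycolysis genes rose with HSPC in both cell types. Against RNA of the added hematopoietic cells stands the median ratio of the rise in stroma to that in endothelium, 2.16 over the 20 hypoxia genes (from 0.686, 0.6855 in full) but 0.323 over 14 listed granulocyte and monocyte genes (up to 1.39), those below 5 FPKM alone, at 5 or more with HSPC and higher with HSPC in both cell types. These ranges overlap and such cells may differ between the cultures, so that source stays open. Scaling between libraries was excluded, with at least 19 of the 20 genes higher in each cell type under every scaling. It also stays open whether each condition was grown on one day or in one vessel, because the lowest correlation within these groups, 0.995 (0.9947), was above the 0.954 (0.9539) of the cultured libraries but no higher than the 0.995 (0.9948) within the in vivo groups. A response of the cells to HSPC stays open as well, and oxygen and cell density were not stated and not tested.

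Erythroid and granulocyte transcripts were high in stroma in vivo. Of 33 listed genes 32 were higher than in cultured stroma, which restates the pattern, so RNA of erythroid and granulocytic cells in these libraries stays open. The median log2 difference of endothelium minus stroma in vivo was -3.72 for erythroid but 0.85 for lymphoid markers. The lymphoid list did not pass there (camera adjusted p from 0.0988 to 0.574 over the alternatives). Its member Cd74 also stood at 67.1 FPKM in endothelium alone, without HSPC. The test therefore cannot exclude carry-over of all blood cells alike, which stays open. Which share of the other stromal differences these cells brought stays open.

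Xist and Y-linked transcripts differed among the cultured libraries. A mix of male and female cells in the 3 libraries with Xist was excluded, since the highest Y-linked value there was 0 FPKM against at least 30.7 elsewhere, while Xist at 1.4 to 2.35 beside Y-linked genes in the other cultured libraries leaves traces of female RNA open. All 24 libraries carried either Xist or all 4 Y-linked genes at 10 FPKM or more, which restates the pattern, so donors of different sex stay open. Without the 3 libraries with Xist, 4439 genes differed between the cultured cell types, 3920 between endothelium alone and in culture, and 6501 between stroma alone and in culture, with 1 cultured endothelial library left that is assumed to vary like the other groups. Sex, donor and culture batch cannot be told apart here, and no biological explanation was tested.

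For each comparison of 3 against 3 libraries only 10 splits exist, too few for a share under 0.05. In each of these 10 comparisons 1 split, the real one, called as many genes. For the cultured cell types the highest other split called 399 genes against 5765, and in the remaining 9 the highest other split called between 1 and 5. For the interactions 100 splits were drawn of 200 possible. In each, 2 splits called as many genes as the real one, the real one included. The other was the split that exchanged all endothelial labels and no stromal ones, with 9954 genes against 5000 for culture and in vivo and 8678 against 7996 for HSPC. That split adds the changes of both cell types, a structure of the design, so changes shared by the cell types raise its count.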

How the results depend on the processing

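The alternatives without the libraries that carry Xist, and with only genes at a mean FPKM of at least 1 without HSPC, were chosen after the result was seen. Counts of called genes and of lists, and both correlations, stayed within 1.5 times or within their spread in 220 cases and moved in 25. Scaling turned the balance of calls, as the report gives for 6 comparisons. Elsewhere the share higher in endothelium went from 52.0% (51.95%) to 46.8% for the cultured cell types, from 50.4% (50.45%) to 48.3% alone and from 54.7% to 49.5% with HSPC under trimmed-mean scaling, and from 49% to 51.2% for the in vivo interaction under quantile normalization. Unless said otherwise the cause was not tested. A limit of 2-fold removes smaller changes by construction and left 3521 genes for the cultured cell types, 4845 in vivo, 4740 for endothelium and 4991 for stroma in vivo against culture. It left 1018 and 1553 for HSPC in endothelium and stroma, 1920 for their interaction, 5174 and 5440 for the cell types alone and with HSPC, and 1543 and 2614 for endothelium and stroma alone against culture. With all 8 groups in the fit, the in vivo interaction called 7654, HSPC in endothelium 1852, HSPC in stroma 3591, their interaction 2276 and endothelium alone against culture 5910. The cultured cell types gave 2801 with only the compared groups and 3546 with a weight per group. With an estimated correlation 12 of 135 list calls were left.

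Leave-one-out gave 1593 (without replicate 2 of endothelium alone) to 4448 (without cultured endothelial replicate 1) for endothelium alone against culture, and 3070 (without replicate 1 of stroma alone) to 5683 (without cultured stromal replicate 1) for stroma. Leaving out any of the 3 libraries alone moved these counts, in endothelium to at most 1671 and in stroma to at most 3152. In endothelium 4448, 3108 and 3136 genes were called without cultured replicates 1 to 3, and in stroma 5683, 3647 and 4123. These samples were as small, so sample size by itself does not account for the fall. Elsewhere the lowest and highest were 4325 to 7140 for the cultured cell types, 5750 to 6134 in vivo and 3627 to 6636 for the in vivo interaction. They were 5735 to 6133 and 7736 to 8624 for HSPC in endothelium and stroma and 7274 to 8381 for their interaction. The correlations ran from 0.4815 to 0.5235 and from 0.322 to 0.3445 across genes, which are not independent replicates.

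With the replicate number as a block (replicate block), 5422 genes were called for the cultured cell types, 7014 in vivo, 6725 and 8419 for HSPC in endothelium and stroma, and 2754 and 4326 for alone against culture. The numbers did not pair libraries: in 0 of 18 pairs of groups did every library correlate best with its own number. Over lists, 125 of 135 calls were kept with a pseudocount of 0.1, 124 with trimmed-mean scaling and 135 with the block, and 0 reversed. Of the values for named genes, 3574 stayed the same, 28 lost their call and 4 gained one. Depth is unknown, so how far it limits the low genes could not be measured.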

Other observations

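The test below was chosen after the result was seen. The co-culture libraries may share their source with replicate 1 of the cultured libraries of their cell type. In each group the libraries correlated most closely with replicate 1. Endothelium alone had 0.9543 or more against at most 0.9338 with replicates 2 and 3. Endothelium with HSPC had 0.9329 or more against at most 0.923. For stroma the values were 0.888 against 0.883 alone and 0.879 against 0.868 with HSPC, across genes, which are not independent replicates. Over both groups of a cell type the ranges overlapped, since the lowest with replicate 1 was 0.933 against 0.934 in endothelium and 0.879 against 0.883 in stroma, so the test leaves a shared source open. A shared sex of the cells could give the same order in endothelium, where replicate 1 is the one without Xist. Genotypes or culture records would decide it.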
